A study of Mus musculus with 59 samples.

How the data were processed

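The deposited table gives read counts for 59 libraries of polyA RNA from C57BL/6 mice. Per the labels, mice were given an intraperitoneal injection of the peptide combination named IP118/PY115 or of vehicle and were killed 4 h later. Brains were frozen and sectioned at 10 µm, and laser capture isolated 4 mm² of tissue from each of 3 regions per animal. The regions were the paraventricular nucleus of the hypothalamus (PVN), the arcuate nucleus of the hypothalamus (ARC) and the nucleus of the solitary tract (NTS). Libraries were made with a stranded mRNA kit on an automated instrument. The labels give the treatment and region of each library but do not tie libraries to animals, so no term for the animal was fitted. Libraries of different regions came from shared animals, and p-values for differences between regions take them as independent.

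The values are raw counts per Ensembl gene and library, as deposited by the authors, who demultiplexed the reads with bcl2fastq 2.20.0.422 and aligned them to GRCm38 with STAR 2.5.2a. The read counter, its strand setting, the annotation release and any filter on genes are not stated. The table holds 21935 Ensembl IDs, of which 21858 were matched to a mouse annotation and 77 were not. Of these 21736 were protein coding, 2834 had no count in any library, and no mitochondrially encoded gene was present. Symbols and coordinates come from that annotation, and 3 symbols belonged to more than 1 ID. Library totals ran from 3964093 to 28510118 counts. Totals did not differ detectably between treatments: the mean log10 total was higher with IP118/PY115 by 0.12 in PVN (adjusted p = 0.265, permutation test), by 0.07 in ARC (adjusted p = 0.265, exact permutation test) and by 0.08 in NTS (adjusted p = 0.354, permutation test).

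Libraries were grouped by region and treatment as the labels state: 10 vehicle and 10 treated libraries in PVN, 9 and 10 in ARC, 10 and 10 in NTS. Replicates are numbered within each group in the order in which they were deposited. Every library was kept under its deposited label unless stated otherwise. Each region was fitted alone with edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10, minimum total count 15) and TMM scaling, with the robust quasi-likelihood test. Genes with a Benjamini-Hochberg adjusted p (FDR) under 0.05 were called, and all tests were two-sided. The treatment effect in a region against that in another, and the vehicle groups of 2 regions, were compared in a joint fit of the 59 libraries. Levels are CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD over the libraries of a group, and fold changes are log2 values of IP118/PY115 over vehicle, given ± SE; intervals cover the spread between libraries and not PCR duplication.

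Before the data were examined, 37 gene lists were fixed, covering neuronal activity, appetite peptides and receptors, region and cell type markers, glucocorticoid response, circadian clock, metabolism, inflammation and stress. Lists with fewer than 3 expressed members in a region were not tested there, which left 32 lists in PVN, 32 in ARC and 33 in NTS and removed those for ventromedial hypothalamus, serotonin neurons, pituitary and mitochondrially encoded genes everywhere. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 97 tests, and again with camera at an estimated correlation and with fry. Mean log2 CPM of each list per library was compared by permutation with 100000 resamples, or exactly in ARC, in a test added after seeing the data.

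The genes named were chosen by a rule fixed beforehand. Where more than 24 genes passed, these were the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM; where fewer than 10 passed, the 10 genes with the smallest p, stated as not passing. Named whatever their values were Glp1r, Npy2r, Agrp, Npy, Pomc, Cartpt, Fos, Avp, Oxt, Crh, Trh, Gcg and Th. Up to 4 members with the smallest p were named for a list past camera and up to 2 for other lists, with up to 10 genes per difference between regions, the region markers, and per vehicle contrast and direction the 5 largest differences among genes with a mean of at least 20 CPM. Other genes named, such as Fosb in NTS, Cdkn1a in PVN and the examples shared by the regions, were chosen after their values were seen. Some genes that these rules name are not reported here and were left out of the search for libraries far from their group; the gene lists keep them.

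Alternatives set beforehand were DESeq2 1.42.0, limma-voom with quality weights, RLE size factors, library totals alone, no filter, a filter of 20 counts in 9 libraries, an FDR of 0.1, a test against a 1.2-fold change, 2 surrogate variables from sva 3.50.0, covariates for log10 library total, for library number rank and for oligodendrocyte and region marker scores. Others were fits without libraries under 0.5 of the region's median total and without the vehicle libraries numbered 5553 to 5557. Those PVN and ARC libraries are numbered apart from the rest of their regions and are all vehicle. Any difference that goes with their numbers is thus tied to treatment. Further fits took all regions together, took only the 2 regions compared, or left out each library in turn. The fits without the libraries numbered 1, the placement of each library on genes picked without it, and the exchange of the labels of every vehicle and treated pair were added after seeing the data.

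The pipeline was tested on simulated counts with known changes. In PVN it recovered 90.9% of 1.5-fold and 93.8% of 2-fold changes. In ARC it recovered 73.1% and 86.6%, in NTS 82.1% and 93.9%, and for a PVN against ARC difference 58.2% and 79.1%. Of the genes called in these 4 comparisons, 5.56%, 3.98%, 2.67% and 6.25% were unchanged ones. Every simulated library was drawn from its own group. The real groups each hold a library on the other group's side, so these rates may overstate what the real fits recover. The shifted list was found in each region and 0 of 40 unchanged lists were called by camera. The simulated genes were drawn independently, so this check does not cover lists whose members vary together. In the draw made for the PVN against ARC difference, treatment changed no gene in ARC or NTS. For the ARC against NTS treatment difference edgeR called 0 genes there.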

Results

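Gene expression was measured by RNA sequencing in laser-captured PVN, ARC and NTS, areas that control feeding and respond to gut hormones. The series concerns joint activation of receptors for the gut hormones PYY and glucagon-like peptide, and asks how a single dose of IP118/PY115 changes these areas. The 59 libraries comprised 20 from PVN, 19 from ARC and 20 from NTS. Median totals were 10491077 counts in PVN, 10392473 in ARC and 11700302 in NTS.

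In vehicle mice the 3 dissections carried the genes that mark each nucleus. In PVN the vasopressin gene Avp stood at 6267 ± 2968 CPM (SD, n = 10), against 37.05 ± 73.4 in ARC (n = 9) and 0 in NTS (n = 10). The corticotropin-releasing hormone gene Crh stood there at 213 ± 52.3 CPM, against 0.0542 in ARC and 2.97 in NTS. In ARC the hunger peptide gene Agrp stood at 595 ± 158 CPM, against 1.75 in PVN and 0.248 in NTS. Pomc, the precursor of melanocortin satiety peptides, stood at 700.3 ± 122 CPM, against 5.89 and 5.12. In NTS, Dbh, which encodes the noradrenaline-making enzyme, stood at 183 ± 36.7 CPM, against 0.311 in PVN and 1.57 in ARC.

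Of the marker lists fixed beforehand, 7 of 8 PVN genes, 11 of 11 ARC genes and 14 of 15 NTS genes were higher in their own region than in both others. The exceptions were the bombesin-like receptor Brs3, at 8.07 CPM in PVN and 25.2 CPM in ARC, and the calcitonin receptor Calcr, at 17.4 CPM in NTS against 203 CPM in PVN and 164 CPM in ARC. The vehicle groups differed in 6610 of 14379 genes between PVN and ARC, in 8064 between PVN and NTS and in 8874 between ARC and NTS. Scaling by library totals alone turned the balance of directions: PVN over ARC went from 3572 higher and 3038 lower to 2849 and 4006, PVN over NTS from 4070 and 3994 to 3539 and 4469, and ARC over NTS from 4345 and 4529 to 4658 and 4287. Patterning genes were among the largest differences between regions: Hoxa5 stood at 359 CPM and Hoxb5 at 295 CPM in NTS and at 0 in PVN and ARC, while Sim1, needed to form the PVN, stood at 134.5 CPM there.

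**Figure D1:**
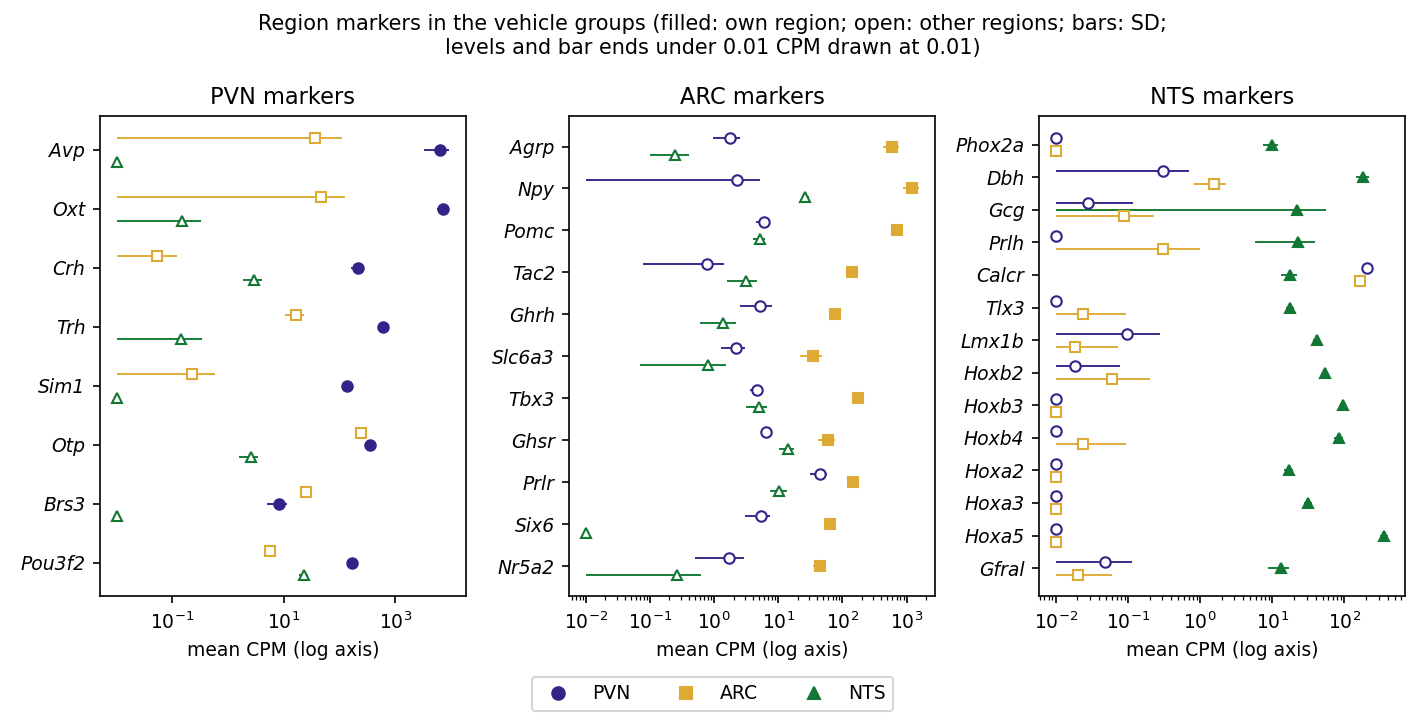
Mean levels (CPM, log axis) of region marker genes in the vehicle groups of PVN (n = 10), ARC (n = 9) and NTS (n = 10), with SD bars; filled symbols are the gene's own region, and values under 0.01 CPM are drawn at 0.01. Apart from Brs3 and Calcr, each filled symbol lies to the right of the open ones.

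In all 3 regions, the vehicle library numbered 1 and the treated library numbered 1 lay on the side of the other group. Each library was placed on the 50 genes of smallest p picked without it, outside the stress and activity lists, with negative values on the vehicle side and positive on the treated side. There vehicle 1 was placed at 0.852 in PVN, 0.968 in ARC and 1.12 in NTS. The treated library numbered 1 was placed at -0.948, -0.683 and -1.14. The other vehicle libraries ran from -1.12 to -0.0870 in PVN, from -0.839 to 0.0377 in ARC and from -0.966 to -0.120 in NTS. The other treated libraries were all positive, from 0.0326, 0.148 and 0.308 upward. In NTS, the activity gene Fosb stood at 39.8 CPM in vehicle 1 and at 0.141 to 2.71 CPM in the other 9 vehicle libraries. It stood at 0.862 CPM in treated 1 and at 18.96 to 48.99 CPM in the other 9 treated libraries. All values are given under the deposited labels. Counts of called genes, and some list and gene values, are also given without these 6 libraries, an alternative added after seeing the data. Because those libraries were picked from the outcome, p-values without them are too small.

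**Figure D2:**
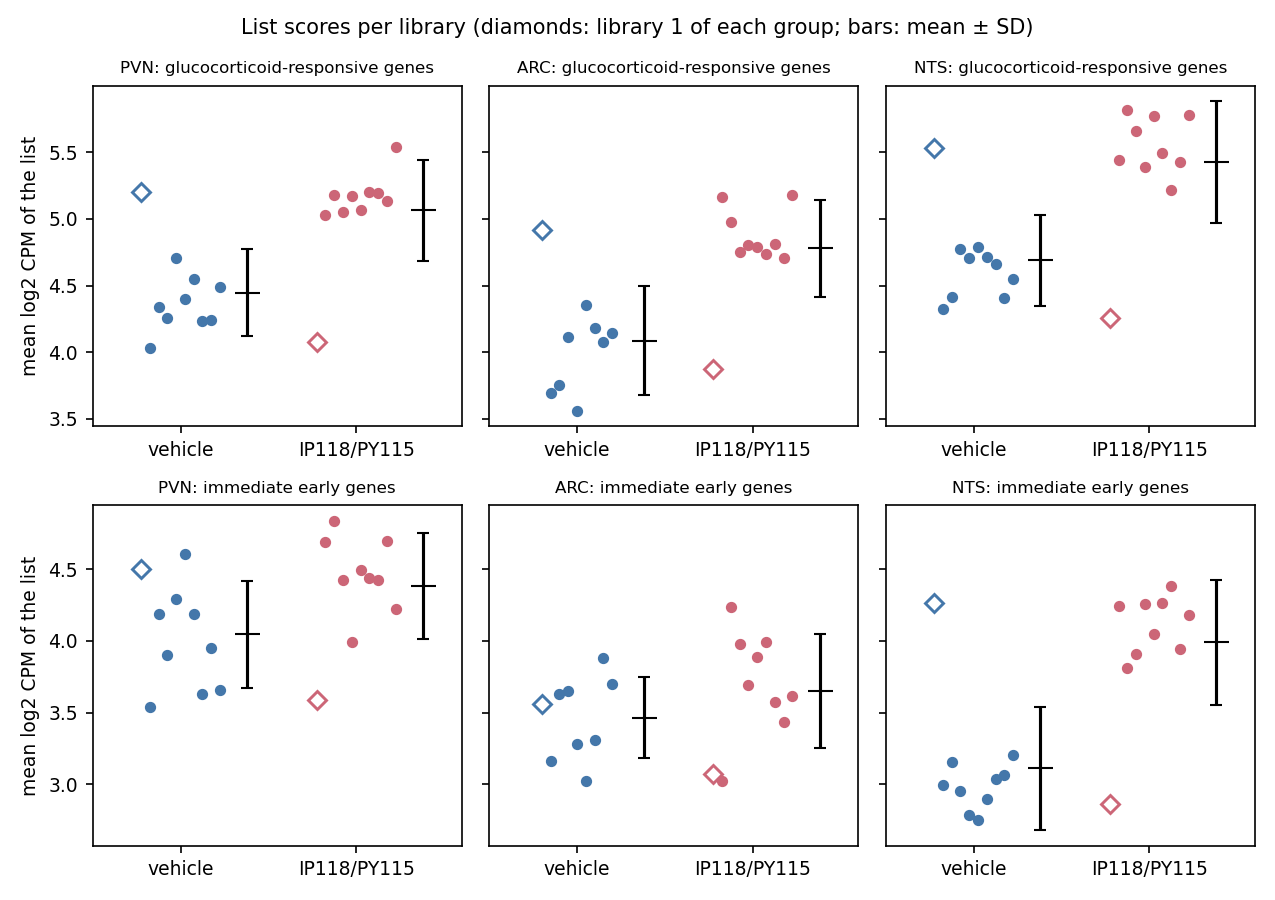
Mean log2 CPM of the glucocorticoid-responsive genes (top) and the immediate early genes (bottom) in each library of the 3 regions, vehicle against IP118/PY115; bars are mean ± SD and open diamonds are the library numbered 1 of each group. In NTS, vehicle 1 has an immediate early score of 4.26, above the other 9 vehicle libraries at 2.75 to 3.20.

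In PVN, 71 genes rose and 17 fell after IP118/PY115. Hs3st2, which encodes a heparan sulfate sulfotransferase, rose from 4.81 ± 4.20 to 18.9 ± 7.35 CPM (SD, n = 10 each; log2 fold change 1.86 ± 0.38), and Nptx2, an activity-regulated synaptic pentraxin, from 13.4 ± 7.06 to 34.9 ± 12.6 CPM (1.33 ± 0.28). Zbtb16, a transcription factor induced by glucocorticoids, rose from 26.1 ± 9.92 to 58.7 ± 12.1 CPM and was above the vehicle median in 10 of 10 treated libraries (1.13 ± 0.19, FDR = 0.0149). The serine protease gene Prss23 had the smallest FDR, 6.5e-04, and rose from 7.57 ± 1.503 to 15.1 ± 3.24 CPM (0.98 ± 0.13, 10 of 10 libraries). The falls were smaller, and included Pou3f2, a transcription factor of PVN neurons, from 167 ± 22.8 to 136 ± 12.97 CPM (-0.30 ± 0.07), and Neurod2, a neuronal transcription factor (-0.73 ± 0.16).

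By edgeR, 88 of 13409 genes were called in PVN, 71 higher and 17 lower. The other named rises were the ephrin receptor Epha2 (1.34 ± 0.28), the matricellular factor Ccn2 (1.23 ± 0.27), Fam107b (1.22 ± 0.26), Rasl11b (0.99 ± 0.21), Tbc1d8b (0.92 ± 0.19), the kinase Map3k6 (0.90 ± 0.17), the cadherin Cdh6 (0.89 ± 0.20) and Fam117a (0.87 ± 0.19). Among the other named falls were Ahnak2 (-0.83 ± 0.15), Inka2 (-0.69 ± 0.15), the ephrin receptor Ephb3 (-0.65 ± 0.14), Plekho2 (-0.64 ± 0.14) and the exchange factor Arhgef19 (-0.47 ± 0.11). The rest were Bahcc1 (-0.43 ± 0.10), Cxxc5 (-0.42 ± 0.10), the zinc finger genes Zfp703 (-0.40 ± 0.09) and Zfp467 (-0.34 ± 0.08), and the membrane-bending protein gene Mtss1l (-0.34 ± 0.07). Called members of other lists were Ghsr, the ghrelin receptor (0.69 ± 0.14), and Cyp51, a sterol demethylase of cholesterol synthesis (0.55 ± 0.11). On GRCm38, Prss23 (ENSMUSG00000039405) lies on chromosome 7 at 89507783 to 89527187, Zbtb16 (ENSMUSG00000066687) on chromosome 9 at 48654297 to 48836222, Hs3st2 (ENSMUSG00000046321) on chromosome 7 at 121391859 to 121501770 and Nptx2 (ENSMUSG00000059991) on chromosome 5 at 144545902 to 144557478.

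**Figure D3:**
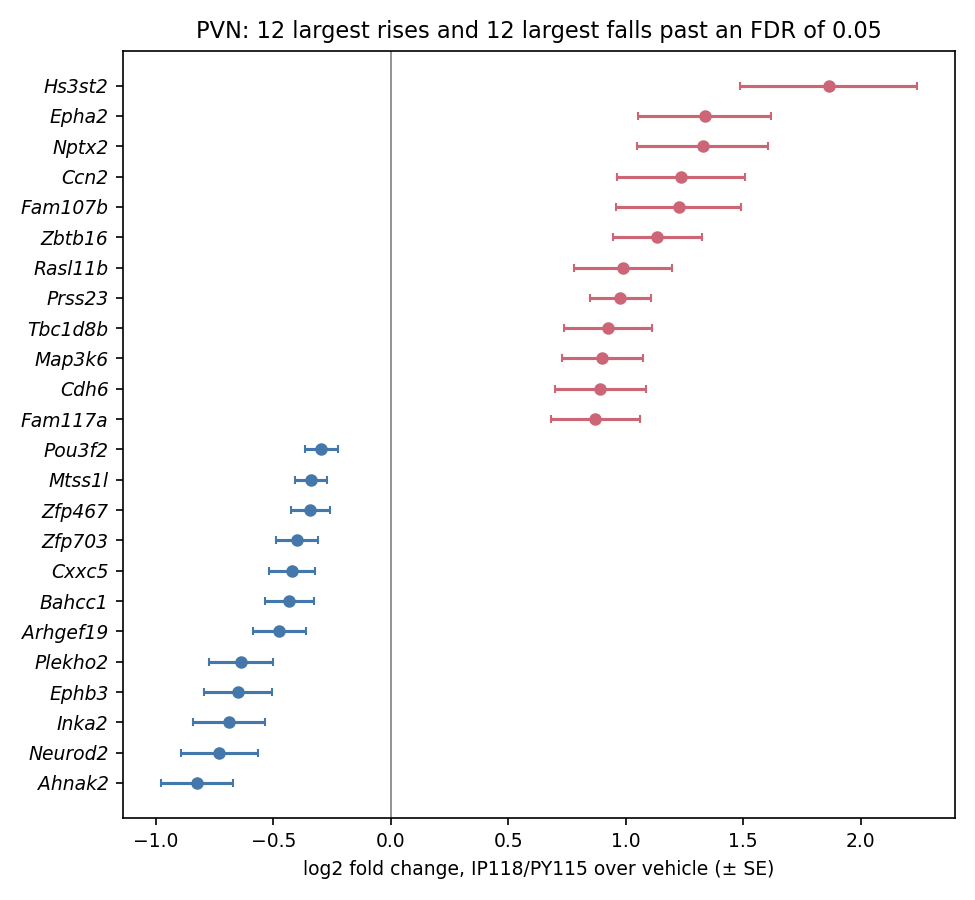
Log2 fold change (IP118/PY115 over vehicle, ± SE, n = 10 each) of the 12 largest rises and 12 largest falls among called PVN genes. Estimates run from -0.83 for Ahnak2 to 1.86 for Hs3st2.

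In PVN, the glucocorticoid-responsive genes rose as a list: 18 of 18 measured members were higher, with a median log2 fold change of 0.50 (camera adjusted p = 1.0e-22; adjusted p = 0.0413 with an estimated correlation; fry adjusted p = 0.0199). Of these, 15 passed when adjusted over the list alone and 3 over all genes, Zbtb16, Map3k6 and the receptor co-chaperone gene Fkbp5, which went from 59.1 ± 15.9 to 93.3 ± 20.7 CPM. Without the libraries numbered 1 the median was 0.63 and 16 members passed over all genes. The mean list score was above the vehicle median in 9 of 10 treated libraries (difference 0.62, permutation adjusted p = 0.0338). Another 7 lists passed camera and lost the call with an estimated correlation. Upward these were immediate early genes (16 of 22 higher, adjusted p = 0.530 with an estimated correlation), late activity-regulated genes (12 of 16, 0.372), the unfolded protein response (12 of 13, 0.153; fry adjusted p = 0.0310), red blood cell genes (5 of 5, 0.649) and inflammation (8 of 9, 0.429). Downward they were astrocyte markers (10 of 11 lower, 0.763) and circadian clock genes (11 of 17 lower, 0.429). Of these 7 lists, only the unfolded protein response passed by permutation of mean list scores (adjusted p = 0.0377).

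When adjusted over the list alone, 4 immediate early genes passed in PVN, all transcription or synaptic regulators: Fosb stood at 7.23 ± 6.79 CPM in vehicle and 24.4 ± 12.9 CPM in treated libraries. The log2 fold changes were 1.12 ± 0.29 for Maff, 1.04 ± 0.27 for Arc and 0.72 ± 0.22 for Fosl2. The secreted neuropeptide precursor Vgf stood at 482 ± 131 and 673 ± 148 CPM. None of these 5 passed over all genes. Of the clock genes, 5 were lower and 2 higher when adjusted over the list alone; Hlf (-0.30 ± 0.08), Nr1d1 (-0.32 ± 0.08) and Dbp (-0.35 ± 0.10) had the smallest p. The hormone genes of the nucleus did not pass: Crh stood at 208 ± 51.04 CPM in vehicle and 241 ± 61.3 CPM in treated libraries (FDR = 0.792), Avp at 6124 ± 2897 and 5973 ± 1216 CPM, and Oxt at 6934 ± 1536 and 7438 ± 1157 CPM. Nor did the receptor genes Glp1r, at 14.8 ± 6.49 and 15.6 ± 2.96 CPM, and Npy2r, at 29.1 ± 9.70 and 23.3 ± 5.20 CPM.

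The PVN count ran from 8 to 276 over fits that left out 1 library, and was 206 by DESeq2. It fell to 6 with log10 library total as a covariate and to 9 without vehicle 3 and 8, which had the smallest totals. Of the 24 largest rises and falls named, 22 lost the call with log10 library total, and 21 with oligodendrocyte and region marker covariates. Without the vehicle libraries numbered 5553 to 5557, 21 lost it. For most of these genes, tissue composition and differences tied to those libraries are thus not excluded. Without the libraries numbered 1, 429 genes were called, 309 higher and 120 lower, which included all 88.

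In ARC, glucocorticoid-responsive genes were higher after IP118/PY115, while no single gene passed. All 18 measured members were higher, with a median log2 fold change of 0.62 (n = 9 vehicle and 10 treated; limma camera adjusted p = 9.4e-25; adjusted p = 0.0285 with an estimated correlation; fry adjusted p = 0.0199). In vehicle and treated libraries, values were 2.69 ± 1.92 and 6.90 ± 2.06 CPM for the hypoxia-inducible factor gene Hif3a, 6.16 ± 3.66 and 14.4 ± 4.58 CPM for the cell cycle inhibitor gene Cdkn1a. They were 19.5 ± 12.2 and 44.3 ± 12.6 CPM for Zbtb16, and 56.8 ± 9.55 and 76.0 ± 12.9 CPM for the transcription factor gene Klf9. Adjusted over the list alone 13 members passed, and 0 over all genes; without the libraries numbered 1 the median was 0.80 and 11 passed over all genes by edgeR. The mean list score was above the vehicle median in 9 of 10 treated libraries (difference 0.69, exact permutation adjusted p = 0.0338).

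By edgeR, 0 of 13484 genes were called in ARC, with 971 at an unadjusted p under 0.05; DESeq2 called 59 and limma-voom with quality weights 5. The 10 genes with the smallest p did not pass (FDR 0.0656 to 0.0896). They were the exchange factors Fgd3 (-0.61 ± 0.12) and Arhgef3 (0.54 ± 0.10), the rhythmic gene Noct (nocturnin) (0.42 ± 0.08), Ric1 (0.37 ± 0.07), Sertm1 (0.43 ± 0.09), the interleukin receptor subunit Il1rap (0.45 ± 0.09). The rest were the adaptor Appl2 (0.29 ± 0.06), Sh3yl1 (-0.42 ± 0.09), the oligosaccharyltransferase subunit Stt3b (0.30 ± 0.07) and the transcription factor Klf13 (0.48 ± 0.10). The feeding genes of the nucleus did not pass by edgeR. Agrp stood at 609 ± 163 CPM in vehicle and 531 ± 147 CPM in treated libraries, Npy at 1243 ± 336 and 1132 ± 237, Pomc at 717 ± 125 and 728 ± 185, and Cartpt at 271 ± 47.4 and 271 ± 55.7. The PYY receptor gene Npy2r stood at 202 ± 33.9 and 160.1 ± 37.1 CPM (edgeR FDR = 0.558), and Glp1r at 9.61 ± 4.09 and 8.99 ± 2.38 CPM.

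Another 7 ARC lists passed camera and lost the call with an estimated correlation. Mature oligodendrocyte markers, genes of myelin-forming cells, were higher in 11 of 11 members (median 1.01, adjusted p = 0.683 with an estimated correlation): Mobp stood at 71.2 ± 38.6 CPM in vehicle and 186 ± 268 CPM in treated libraries, with treated library 2 at 915 CPM. Late activity-regulated genes (13 of 15, 0.272) and red blood cell genes (5 of 5, 0.675) were also higher. Lower were cytosolic ribosomal proteins (69 of 75 members, adjusted p = 0.794 with an estimated correlation), nuclear-encoded oxidative phosphorylation (61 of 75, 0.762), cholesterol synthesis (14 of 16, 0.683) and microglia markers (10 of 12, 0.538; Cx3cr1 -0.41 ± 0.12). Leaving out vehicle 1 gave 85 called genes, leaving out treated 1 gave 50, and leaving out treated 2 gave 1. Without the libraries numbered 1, 153 genes were called, 110 higher and 43 lower, including Cdkn1a (1.61 ± 0.16) but not Npy2r (-0.44 ± 0.11, edgeR FDR = 0.0550).

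In NTS, genes that neurons switch on when active were higher after IP118/PY115, as were glucocorticoid-responsive genes. All 24 measured immediate early genes were higher, with a median log2 fold change of 0.55 (camera adjusted p = 2.1e-29; adjusted p = 0.0241 with an estimated correlation; fry adjusted p = 0.0199). Fos, the standard marker of neuronal activation, stood at 21.2 ± 19.99 CPM in vehicle and 60.4 ± 23.9 CPM in treated libraries (SD, n = 10 each). The same 2 values were for Junb 25.8 ± 17.2 and 63.9 ± 21.2, for Nr4a1 15.6 ± 8.55 and 40.5 ± 13.4, for Fosb 5.24 ± 12.2 and 28.1 ± 12.5, and for Egr4 1.53 ± 2.01 and 8.30 ± 3.95. Adjusted over the list alone 15 of the 24 passed, and 0 over all genes. When the libraries numbered 1 were left out, 23 of the 24 were higher, the median was 0.71 and 15 passed over all genes. The 18 measured glucocorticoid-responsive genes were all higher, with a median of 0.61 (adjusted p = 0.0241 with an estimated correlation). Of them 17 passed when adjusted over the list alone and 0 over all genes, and Cdkn1a stood at 17.4 ± 14.3 and 48.5 ± 17.7 CPM. For this list the median was 0.80 without the libraries numbered 1, and 17 passed over all genes.

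**Figure D4:**
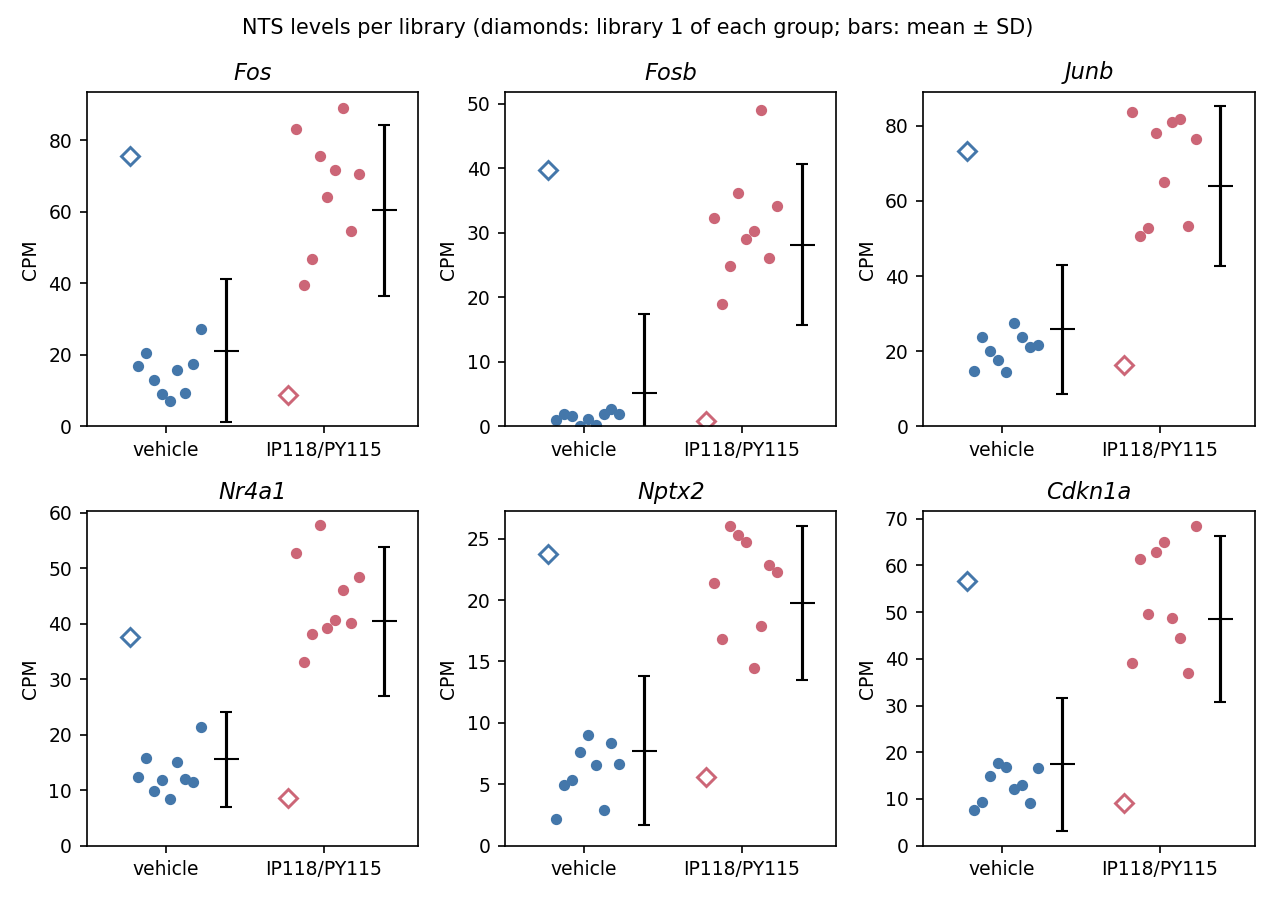
Levels (CPM) of 6 genes in each NTS library, vehicle (n = 10) against IP118/PY115 (n = 10); bars are mean ± SD, drawn from 0 upward, and open diamonds are the library numbered 1 of each group. Apart from the diamonds, Fos lies at 6.98 to 27.1 CPM in vehicle and at 39.6 to 89.1 CPM in treated libraries.

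By edgeR, 0 of 13696 genes were called in NTS, with 795 at an unadjusted p under 0.05; DESeq2 called 67 and limma-voom with quality weights 19. The 10 genes with the smallest p did not pass (FDR 0.0892 to 0.101). They were the kinase Map3k6 (0.99 ± 0.18), the Myc antagonist Mxd4 (0.36 ± 0.07), the endosomal sorting factor Vps37b (-0.41 ± 0.08), Arrdc2 (1.07 ± 0.21) and Egr4 (2.46 ± 0.47). Next came the transcription factor Klf15 (0.46 ± 0.09), the coagulation factor receptor F3 (0.55 ± 0.11), Fam20a (0.44 ± 0.09), the phagocytic receptor Mertk (0.73 ± 0.15) and Midn (0.37 ± 0.08). The appetite genes did not pass: Npy stood at 26.6 ± 3.07 CPM in vehicle and 37.1 ± 11.4 CPM in treated libraries (FDR = 0.255), Npy2r at 36.4 ± 7.69 and 38.6 ± 12.6, and the preproglucagon gene Gcg at 22.5 ± 33.2 and 30.3 ± 46.8. Glp1r had too few counts to be tested in NTS.

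In NTS, 3 further lists passed with an estimated correlation. These are not separate lines of evidence, because the lists share members. Most cAMP and CREB targets are also in the immediate early list, such as Fos and Nr4a1, or the late activity list, such as Vgf. Inflammation shares Nfkbia with the glucocorticoid list. Late activity-regulated genes were higher in 15 of 15 members (median 0.43, adjusted p = 0.0241 with an estimated correlation; Nptx2 7.75 ± 6.04 and 19.7 ± 6.27 CPM), targets of cAMP and CREB in 15 of 18 (median 0.31, 0.0241) and inflammation genes in 5 of 7 (median 0.42, 0.0285), among them the interleukin receptor Il1r1 at 2.95 ± 0.777 and 5.66 ± 2.39 CPM. Lists that passed only the preset correlation were cholesterol synthesis, lower in 15 of 16 members (adjusted p = 0.0733 with an estimated correlation; fry adjusted p = 0.0310; Sqle -0.18 ± 0.05), and the NTS markers, lower in 12 of 15 (0.649). The others were the unfolded protein response, higher in 12 of 14 (0.683), and nuclear-encoded oxidative phosphorylation, higher in 57 of 75 (0.794). By permutation of mean list scores, late activity-regulated genes and cAMP and CREB targets passed (adjusted p = 0.0338 each), while inflammation did not (adjusted p = 0.0924). Of the lists past only the preset correlation, cholesterol synthesis alone passed by permutation (adjusted p = 0.0377). Leaving out vehicle 1 gave 92 called genes and leaving out treated 1 gave 90. Without the libraries numbered 1, 162 genes were called, 135 higher and 27 lower, including Fosb (4.38 ± 0.26) and Fos (2.11 ± 0.23).

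**Figure D5:**
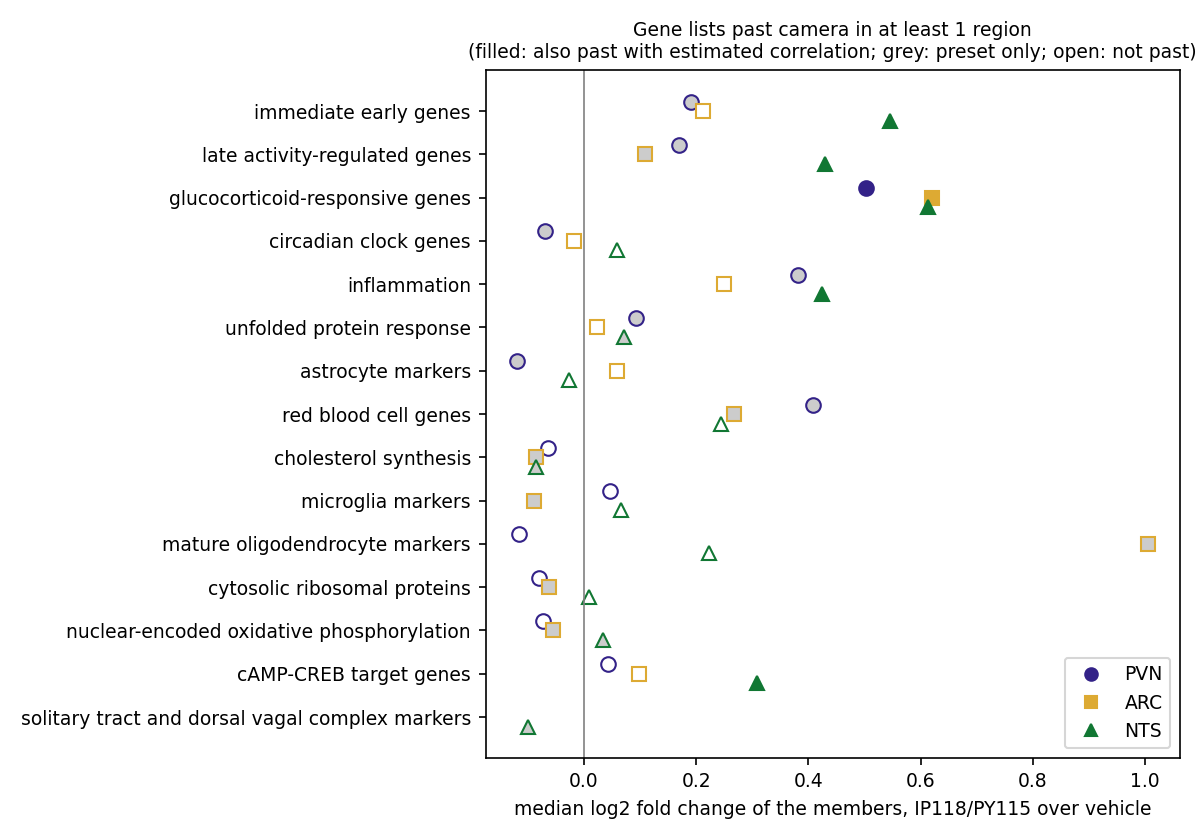
Median log2 fold change (IP118/PY115 over vehicle) of the members of each list past camera in at least 1 region, by region; filled symbols also pass with an estimated correlation, grey ones pass with the preset correlation alone and open ones do not pass. The glucocorticoid-responsive genes lie at 0.50, 0.62 and 0.61 in PVN, ARC and NTS.

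The difference in treatment effect between regions was tested to see which genes responded more in a given nucleus. Between PVN and ARC 7 of 14379 genes differed, 6 with a larger log2 fold change in PVN. Tsc22d1, a transcriptional regulator, was at 0.43 ± 0.06 in PVN and -0.08 ± 0.06 in ARC (FDR = 0.00311), Cyp51 at 0.54 ± 0.08 and -0.03 ± 0.08, and Apobec1, an RNA-editing deaminase, at 0.91 ± 0.21 and -0.58 ± 0.22. Between PVN and NTS 13 genes differed, 12 with a larger change in PVN, among them Cyp51 (-0.11 ± 0.08 in NTS, FDR = 9.8e-04) and Hs3st2 (1.88 ± 0.26 in PVN and 0.23 ± 0.23 in NTS). Between ARC and NTS edgeR called 0 genes, with 540 at an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. Camera at the preset correlation called list differences, such as immediate early genes for ARC against NTS (adjusted p = 3.3e-11) and PVN against NTS (1.3e-05). No list differed with an estimated correlation, where the immediate early genes had an adjusted p of 0.296 for ARC against NTS and of 0.558 for PVN against NTS. The counts depend on the libraries used. Without vehicle libraries 5553 to 5557 edgeR called 0 genes for PVN against ARC (981 at an unadjusted p under 0.05; with all libraries DESeq2 called 16 and limma-voom 20) and 4 for PVN against NTS, and with only the 2 regions compared it called 4 and 2. Without the libraries numbered 1 the counts were 52, 62 and 35. In that last fit p-values are too small, because the libraries left out were picked from their values. Their immediate early scores stood apart in NTS (vehicle 1 at 4.26, treated 1 at 2.87), so leaving them out raises the NTS effect tested. With that limit, the treatment effect on 4 lists, which share members, was larger in NTS than in ARC. They were immediate early (camera adjusted p = 0.00106 with an estimated correlation), late activity-regulated (0.00103), cAMP and CREB target (0.00255) and circadian clock genes (0.0172). Against PVN it was larger in NTS for immediate early (0.0264) and clock genes (0.0208). The clock genes had a median of 0.09 in NTS, -0.08 in PVN and -0.07 in ARC there.

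Across genes, treatment log2 fold changes correlated weakly between regions, with a Pearson r of 0.19 and Spearman rho of 0.13 for PVN and ARC, 0.29 and 0.19 for PVN and NTS, and 0.30 and 0.24 for ARC and NTS; genes are not independent replicates. Of the 88 genes called in PVN, 67 had the same direction in NTS, and of the 85 also tested in ARC, 73 did. The regions share animals, so some likeness between them can arise without a treatment effect, and no chance level was computed for these values.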

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

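Of the tests weighed here, the exchange of labels, the clock genes, the leaving out of single libraries for the immediate early genes, the placement of libraries and the splits in PVN and ARC were chosen after their results were seen; the tissue composition tests, the NTS splits and the splits for differences between regions were not.

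The libraries numbered 1 lie on the other group's side in all 3 regions, and exchanged labels are a candidate explanation that stays open. Exchanging the labels of this vehicle and treated pair gave more called genes than any other pair in 3 of 3 regions (528, 204 and 201, highest other 286, 80 and 81), but this follows from where the libraries lie, whatever put them there. Oligodendrocyte and region marker scores were regressed out to test those parts of tissue composition. All 6 libraries stayed on the other side on the glucocorticoid score, which argues against those parts as the whole cause. In PVN, however, treated 1 went from -0.69 to -0.24 and vehicle 1 from 0.44 to 0.33. Other PVN vehicle libraries then reached up to 0.18 and other treated ones down to -0.02. The labels number these libraries 2 apart, and when numbers are counted from the lowest of each region, the treatment was the same at 19 of the 19 positions that regions share, so the 3 regions may show a single pair of animals and not 3 separate events. A stressed vehicle animal together with an injection that missed could give the same picture and was not tested, so the deposited labels were kept.

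Glucocorticoid-responsive genes were higher in all 3 regions. With oligodendrocyte and region marker scores as covariates, the medians were 0.39 in PVN, 0.53 in ARC and 0.61 in NTS (fry p = 0.0039, 0.0029 and 0.0010). This tests only those parts of tissue composition, since other cell types such as astrocytes and microglia were not covariates. Time of collection stays open: clock output genes moved against opposing clock genes by -0.13 in PVN (95% interval -0.32 to 0.07), -0.05 in ARC (-0.21 to 0.10) and -0.05 in NTS (-0.26 to 0.16), intervals too wide to rule out a shift. A bound of 0.5 log2 units, itself set after the clock genes had been seen, would have excluded it and was replaced by 0.1 once these intervals were known; 0.5 would also pass over changes as large as the -0.35 of the clock gene Dbp in PVN. A rise in circulating corticosterone after the peptides may lie behind the list, and hormone levels are not in the data.

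Immediate early genes were higher in NTS. With the same marker scores as covariates the median was 0.55 (fry p = 6.6e-04). This counts against oligodendrocyte and region marker content as the cause, and other cell types were not tested. No 1 library carries it: the median ran down to 0.51 without vehicle 6 and was 0.63 without vehicle 1. Activation of NTS neurons by the peptides may explain the rise, as a hypothesis from these same data; direct receptor action and input from the vagus nerve were not told apart by any test.

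Other splits of the same libraries were counted for each comparison, with the real split included. In PVN only the real split, 1 of 100, gave as many as 88 genes (highest other 44). No other split reached that count, which argues against random grouping alone, within a test chosen after its result was seen. Exchanging 1 vehicle and 1 treated label could give more: 528 genes for the libraries numbered 1 and 286 for vehicle 1 with treated 9. Exchanges with neither library numbered 1 gave at most 6. The real labels are thus not the grouping with the most genes. Splits also cannot tell treatment from other differences between the groups, such as those tied to the all-vehicle libraries numbered apart. For lists, 35 of 100 PVN splits gave as many as 8 (highest other 13). For ARC 40 of 100 splits gave as many as 8 lists (highest other 14), and in NTS 35 of 100 gave as many as 9 (highest other 12). Chance is thus not excluded for the list counts. No split can give fewer than the 0 genes that edgeR called in ARC (971 at an unadjusted p under 0.05, DESeq2 59, limma-voom 5) and in NTS (795 unadjusted, DESeq2 67, limma-voom 19). That 100 of 100 splits gave as many in both (highest other 1 each) was therefore fixed in advance and says nothing about chance. Counts of genes at an unadjusted p under 0.05 were as large in 8, 20 and 22 of 100 splits in PVN, ARC and NTS. Chance is not excluded for those counts.

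For differences between regions, 2 of 30 splits gave as many as the 7 genes of PVN against ARC (highest other 13), so chance is not excluded. For PVN against NTS only the real split, 1 of 30, gave as many as 13 (highest other 5). These splits took the libraries of shared animals as independent, which they are not, so this does not settle chance. For ARC against NTS, where edgeR called 0 genes (540 unadjusted, DESeq2 3, limma-voom 0), all 30 splits had to give as many, which says nothing about chance. The highest other split there called 93, and the source of that count was not traced. In the vehicle contrasts 1 of 30 splits, the real one, gave as many genes each time. The counts were 6610 for PVN against ARC (highest other 1897), 8064 for PVN against NTS (highest other 0 by edgeR) and 8874 for ARC against NTS (highest other 584). No other split came near them, which argues against chance, though these splits also took shared animals as independent.

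Tests for a library far from the rest, run in 496 groups of libraries, found 102, and 70 of these were libraries numbered 1. Chance gives about 1 in 20 groups if groups are independent. These are not, because many genes vary together and 1 library can be counted many times. Flags on other libraries were not far above that rate, so chance is not excluded for them. The mean log2 CPM of the glucocorticoid-responsive genes was lowest in treated 1 of PVN (4.07, others 5.03 to 5.54), of ARC (3.87, others 4.71 to 5.18) and of NTS (4.25, others 5.22 to 5.82), and highest in vehicle 1 of NTS (5.53, others 4.32 to 4.79). That of the immediate early genes was highest in vehicle 1 of NTS (4.26) and lowest in treated 1 of NTS (2.87, others 3.81 to 4.38).

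Levels of the libraries that stood apart from the rest of their group in PVN are given in CPM. Hs3st2 (16.2), Epha2 (8.69), Cdh6 (9.37), Nptx2 (31.2), Fam107b (53.5), Fkbp5 (96.1) and Nfkbia (49.8) were highest in PVN vehicle 1. Il1r1 (10.9), Cdkn1a (51.4), Cyp51 (196), Tsc22d3 (162), Mertk (26.7), Tsc22d1 (863) and Rnf169 (80.1) were highest in PVN vehicle 1. Mtss1l (175), Bahcc1 (15.1) and Bhlhe40 (37.8) were lowest in PVN vehicle 1. Plekho2 (14.4) and Sox2 (30.4) were highest in PVN treated 1. Rasl11b (7.22), Errfi1 (31.8), Nfkbia (21.3), Cyp51 (116), Tsc22d3 (79.1), Klf9 (52.3) and Per1 (41.7) were lowest in PVN treated 1. Tsc22d1 (557) and Rnf169 (32.5) were lowest in PVN treated 1. Npy (9.97) was highest in PVN vehicle 3. Prss23 (11.1) was highest in PVN vehicle 5. Fosl2 (199.9) was highest in PVN vehicle 6. Plekho2 (26.3), Sox9 (34.4), Slc1a2 (1046) and Aqp4 (140.0) were highest in PVN vehicle 10. Calr (392) was lowest in PVN vehicle 10. Hbb-bt (16.8) was highest in PVN treated 2. Tnfaip3 (7.08) and Icam1 (13.5) were highest in PVN treated 7. Il1r1 (21.5) was highest in PVN treated 10.

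Levels of the libraries that stood apart from the rest of their group in ARC are given in CPM. Noct (79.3), Il1rap (56.1), Stt3b (135), Klf13 (79.1), Klf9 (78.5), Cdkn1a (15.2) and Zbtb16 (50.2) were highest in ARC vehicle 1. Fkbp5 (162) was highest in ARC vehicle 1. Errfi1 (34.5) was lowest in ARC treated 1. Ift57 (31.9) was lowest in ARC vehicle 4. Agrp (1003) was highest in ARC vehicle 6. Avp (231) was highest in ARC vehicle 9. Myrf (61.8), Mobp (915), Insig1 (85.5) and Mal (249.8) were highest in ARC treated 2. Tbx3 (109) was lowest in ARC treated 2. Cartpt (391) was highest in ARC treated 6. Csf1r (84.5) was highest in ARC treated 8. Oxt (195) was highest in ARC treated 9. Fam222b (51.4) was highest in ARC treated 10.

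Levels of the libraries that stood apart from the rest of their group in NTS are given in CPM. Egr4 (7.02), Nr4a1 (37.7), Hif3a (17.97), Nr4a3 (15.8), Junb (73.4), Cdkn1a (56.7) and Nptx2 (23.8) were highest in NTS vehicle 1. Per1 (82.7), Plk2 (69.5), Fos (75.4), Homer1 (42.5), Gcg (102), Fosb (39.8) and Tsc22d3 (229) were highest in NTS vehicle 1. Errfi1 (61.4), Fkbp5 (61.2) and Zbtb16 (25.6) were highest in NTS vehicle 1. Vps37b (15.5) was lowest in NTS vehicle 1. Manf (99.7) and Sox2 (61.5) were highest in NTS treated 1. Klf15 (27.3), Fam20a (19.99), Nr4a1 (8.53), Junb (16.4), Cdkn1a (9.05), Per1 (31.6) and Tsc22d3 (99.8) were lowest in NTS treated 1. Fam117a (16.7) and Pde9a (44.9) were highest in NTS vehicle 7. Prlh (64.9) and Hoxb4 (120.0) were highest in NTS treated 8. Idi1 (4.13) was lowest in NTS treated 8. Crh (56.9) was highest in NTS treated 9. Map3k6 (11.8) was highest in NTS treated 10. Mvd (19.5) was lowest in NTS treated 10.

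The treatment effect differed between PVN and ARC by a test of the difference for Tsc22d1 (0.51), Cyp51 (0.57), Apobec1 (1.49), Tmem200a (0.66), Fam222b (0.43), Appl2 (-0.45) and Ift57 (0.52), as log2 fold change in PVN minus that in ARC. Between PVN and NTS it differed for Cyp51 (0.66), Orc1 (4.23), Fam117a (1.28), Ift57 (0.55), Akap7 (0.62), Fam222b (0.43), Zfp516 (0.73), Hs3st2 (1.64), Pde9a (0.52), Rnf169 (0.74), Trh (-5.31), Prss23 (0.90) and Tmem200a (0.61). The estimates for Orc1 and Trh rest on low levels in NTS: Orc1 stood at 0.281 CPM in vehicle and 0.0930 CPM in treated libraries there, and Trh at 0.145 and 4.78 CPM.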

How the results depend on the processing

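The fits without the libraries numbered 1 and the list counts without each library in turn were chosen after seeing the data. No called gene among those named changed direction, but with library totals alone the balance of higher and lower genes turned in the 3 vehicle contrasts: 2849 and 4006 for PVN over ARC, 3539 and 4469 for PVN over NTS, 4658 and 4287 for ARC over NTS. The cause of each change below was not tested, except that fits without some libraries hold fewer samples.

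With 88 genes in PVN and 0 in ARC and in NTS by edgeR, DESeq2 gave 206, 59 and 67, limma-voom with quality weights 508, 5 and 19, an FDR of 0.1 175, 14 and 6, all 59 libraries in a joint fit 152, 22 and 32, and oligodendrocyte and region marker covariates 11, 27 and 4. With 2 surrogate variables ARC gave 25 and NTS 29. Without the libraries numbered 1 of both groups the counts were 429, 153 and 162. PVN alone also moved with the 1.2-fold test (1), log10 library total (6), without libraries under 0.5 of the median total (9) and without vehicle libraries numbered 5553 to 5557 (12). Of 8, 8 and 9 lists in PVN, ARC and NTS, camera with estimated correlation kept a count of 1, 1 and 5 and fry directional 2 in PVN and 1 in ARC, and 2 surrogate variables gave 5 in PVN.

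Differences between regions, 7, 13 and 0 genes for PVN against ARC, PVN against NTS and ARC against NTS by edgeR, became 52, 62 and 35 without the libraries numbered 1. PVN against ARC was 16 by DESeq2, 4 with no low-count filter, 20 by limma-voom, 4 with only the 2 regions compared and 0 by edgeR without vehicle libraries 5553 to 5557 (981 at an unadjusted p under 0.05). PVN against NTS was 55 by limma-voom, 2 with only the 2 regions compared and 4 without libraries 5553 to 5557, and ARC against NTS was 3 by DESeq2.

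Leaving out each library in turn gave 8 to 276 genes in PVN, 0 to 85 in ARC and 0 to 92 in NTS, and 7 to 11, 5 to 9 and 7 to 11 lists. In PVN the vehicle libraries 1, 2, 3, 4, 6, 8 and 9 gave 276, 39, 10, 17, 18, 25 and 37 genes when left out, and the treated libraries 1 to 8 and 10 gave 263, 43, 19, 56, 30, 32, 9, 8 and 9. In ARC, 85, 50 and 1 came without vehicle 1, treated 1 and treated 2, and in NTS 92 and 90 without vehicle 1 and treated 1; the ARC list count was 5 without vehicle 1. Across settings, called genes were on the same side of the threshold in 229 cases and weaker in 131, and genes not called in 636 and stronger in 91. The settings differed: DESeq2, limma-voom and RLE size factors kept all 24 called genes. The 1.2-fold test lost 23 of them and log10 library total 22. Marker covariates lost 21, as did leaving out libraries under 0.5 of the median total or those numbered 5553 to 5557.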

Other observations

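The overlap of regions without the libraries numbered 1 was computed after seeing the data. Without them, 27 of 12971 genes tested in all 3 regions were higher in all 3, of which 11 are in the glucocorticoid list. The regions share animals and these libraries were left out because of their values, so the overlap has no simple chance level. Log2 fold changes in PVN, ARC and NTS were 2.07, 1.61 and 2.01 for the cell cycle inhibitor Cdkn1a, 1.33, 1.55 and 1.16 for Zbtb16, 0.82, 1.02 and 0.77 for Fkbp5, and 0.58, 0.59 and 0.80 for the glucocorticoid-induced leucine zipper gene Tsc22d3. The 3 genes lower in all 3 included Sox2, a stem cell factor of glia, at -0.80, -0.36 and -0.74.

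Lists that passed camera in no region had these smallest adjusted p: appetite-stimulating peptides 0.211 (NTS), appetite-suppressing peptides 0.150 (PVN), feeding and gut-hormone receptors 0.631 (NTS), arcuate markers 0.350 (ARC), paraventricular markers 0.562 (NTS), brainstem motor nucleus 0.850 (PVN) and catecholamine synthesis 0.347 (ARC). For fasting response it was 0.0756 (PVN), interferon response 0.138 (ARC), heat shock 0.419 (ARC), neurons 0.0685 (NTS), glutamate and GABA neurons 0.150 (PVN), oligodendrocyte precursors 0.159 (ARC), endothelium 0.150 (NTS), mural cells 0.0944 (ARC), ependyma and tanycytes 0.127 (NTS), choroid plexus 0.374 (ARC) and meninges 0.320 (ARC).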
